A study of Mus musculus with 15 samples.

How the data were processed

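Small RNA from whole lungs of 15 C57BL/6 mice was sequenced. WT mice and mice homozygous for the R213G variant of extracellular superoxide dismutase (EC-SOD) received 1 intratracheal dose of bleomycin (100 uL at 1 U/mL) or of phosphate-buffered saline (PBS). Lungs were flushed with PBS through the right ventricle and taken 7 days later. The groups were WT PBS (3 libraries), WT bleomycin (4), R213G PBS (4) and R213G bleomycin (4). Males and females were used, and the sex of each mouse is not given in the sources used here. Each library was treated as a separate mouse, which holds only as far as the labels say.

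The authors extracted total RNA with miRNeasy columns and made Illumina small RNA libraries. The submitters named Bowtie2 2.3.2, SAMtools 1.9 and edgeR in their processing notes, without the genome build or the miRBase release. Per library, the deposited table holds log2 values for 1424 mature miRNAs. From the values themselves, these were taken to be the logarithm of 1 plus a count equalized to a common library size within each group. That is an inference, since the name of the deposited table mentions RPKM and no source used here describes the unit, but the values do not look divided by miRNA length. The deposited table also holds log2 fold changes, which equal the differences of the group means within 7.2e-09, and p-values and q-values of the authors' Welch and Wilcoxon tests. Because of the equalization, a library with 0 reads of a miRNA can hold a small positive value, and the read counts could not be recovered.

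The test planned for counts, an edgeR quasi-likelihood test, was therefore not run. The log2 values were used as they are in limma 3.58.1 (R 4.3.3), with an intensity trend and 1 mean per group over all 15 libraries. In all, 5 contrasts were tested, namely bleomycin against PBS in WT and in R213G, R213G against WT after PBS and after bleomycin, and the genotype by bleomycin interaction. The p-values were adjusted by Benjamini and Hochberg over the tested miRNAs of each contrast, and an adjusted p under 0.05 was called. The plan gave a filter for normalized values but none for log2 values. The one adopted kept miRNAs with an equalized count above 5 in at least 3 libraries, which left 818. No 2 tested miRNAs had identical values in every library.

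The tests, the 19 miRNA lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The rule took, per contrast, up to 12 rising and 12 falling miRNAs with the smallest p among those called, or the 5 with the smallest p where fewer than 5 were called. It added up to 4 members per list with the smallest p. It also added miR-21a-5p, miR-155-5p, miR-146a-5p, miR-223-3p, miR-29b-3p, miR-34a-5p, miR-126a-3p, miR-451a, miR-200c-3p and let-7d-5p, whatever their result. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 19 lists of a contrast. Camera with a correlation estimated per list and fry, which asks whether members move 1 way, were run beside it. The lists covered pro-fibrotic, anti-fibrotic, NF-kB-linked, myeloid, lymphocyte, erythroid, endothelial, epithelial, ciliated cell, smooth muscle, striated muscle, other-organ, proliferation, p53, hypoxia and redox, let-7, miR-30, Dlk1-Dio3 and Sfmbt2 miRNAs. Some miRNAs stand in more than 1 list: 6 of the 14 tested pro-fibrotic, 6 of the 15 anti-fibrotic, 5 of the 9 erythroid, 5 of the 10 p53 and 6 of the 9 hypoxia and redox members. All tested members passed the filter in whole lung, and expression by cell type was not analysed here, so a list marks no cell type by itself. Of the listed miRNAs, miR-424-5p and miR-145b are not in the table, and miR-206-3p did not pass the filter.

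Values summed to between 18087289.8 and 24759615.3 equalized counts per library. These sums are not read depths, which are not given in the sources used here, so no counting interval was computed. The value taken by a single read, read off miRNAs at the floor, lay between 0.734 and 1.283 across libraries. The median half-width of the 95% confidence interval of a log2 difference was 0.51 for the WT response, 0.48 for the R213G response and 0.70 for the interaction. Over the 287 miRNAs with a mean above log2 8 these were 0.29, 0.27 and 0.40. The procedure was tested on simulated data with 200 changed miRNAs in the same design. At a log2 change of 1 it recovered 69.7% of them in the WT contrast, 75.8% in the R213G contrast and 55.4% in the interaction, with false calls between 2.34% and 5.92%. The simulated noise was independent between miRNAs. Where fewer miRNAs change, the adjusted threshold is stricter and these shares would be lower.

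Alternatives covered leaving out each library, the filter, the pseudocount, the scaling (equal medians or quantile normalization), the trend, array weights, a replicate term, the 2 compared groups alone and an adjusted p under 0.1. A covariate for depth and a term for tag order were added after the data were seen. The tag numbers in the column names may mark an order of mice or libraries, which the labels do not explain, and the term set the first 2 tags of each group against the rest. Alternatives that need counts were not applicable. Neighbouring miRNA genes and host genes were taken from GENCODE M21 (mouse assembly GRCm38), which matched 1375 of the 1424 miRNAs by name. Of these, 88 lie in more than 1 place and were not used. Coordinates are not printed because the authors' build is not given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.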

Results

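The libraries describe how lung miRNAs differ 7 days after bleomycin, a DNA-damaging drug used to injure the lung, in mice with and without a common variant of EC-SOD. EC-SOD is the antioxidant enzyme of the extracellular space, and the R213G form binds less tightly to the matrix. The 15 libraries fell into WT PBS (n = 3), WT bleomycin (n = 4), R213G PBS (n = 4) and R213G bleomycin (n = 4). Equalized counts summed to between 18087289.8 and 24759615.3 per library. In every library miR-143-3p, a smooth muscle miRNA, was the most abundant, with 12.0% to 15.8% of the sum. Values below are log2 of 1 plus the equalized count. Of 1424 mature miRNAs in the table, 818 passed the filter and were tested.

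The first principal component, with 44.0% of the variance, separated bleomycin from PBS libraries. PBS libraries scored from -13.69 to -10.23, except WT PBS replicate 3 at -7.26, and bleomycin libraries from 6.33 to 11.85. On the second component (10.6%), R213G PBS replicates 1 and 3 scored -6.00 and -5.76, and replicates 2 and 4 scored 5.87 and 5.56. Genotype separated on neither.

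**Figure D1:**
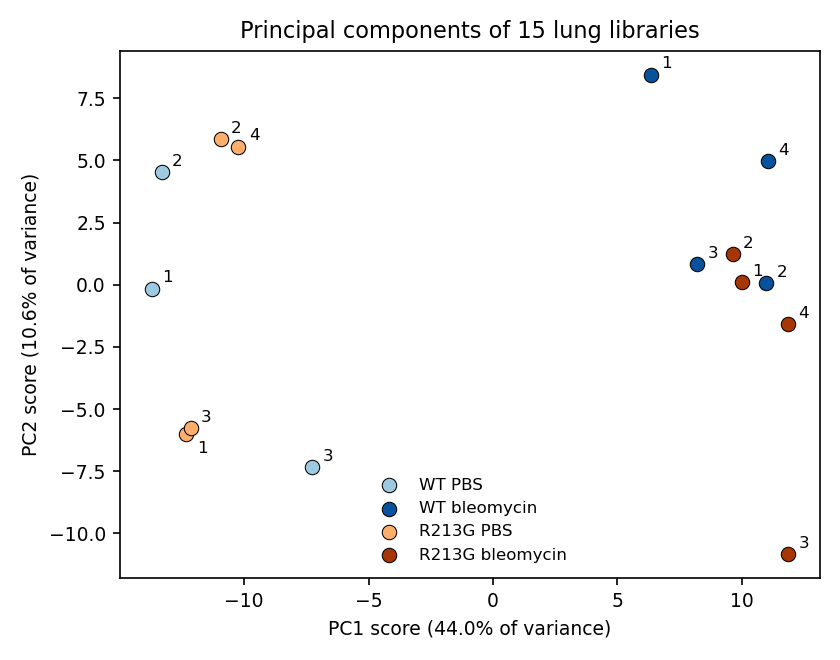
Principal component scores of the 15 lung libraries over 818 miRNAs, coloured by group and numbered by replicate. PC1 (44.0% of variance) parts PBS libraries, at or below -7.26, from bleomycin libraries, at or above 6.33.

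Bleomycin against PBS in WT mice shows which lung miRNAs differ at this stage of injury with an unchanged EC-SOD. The miRNA miR-21a-5p, long linked to fibrosis and inflammation, rose from 17.96 ± 0.37 (SD, n = 3) to 19.90 ± 0.19 (SD, n = 4), a log2 difference of 1.94 ± 0.14 (SE, adjusted p = 5.13e-08). Its partner strand miR-21a-3p rose by 2.50 ± 0.17 (SE, adjusted p = 4.27e-08). The neighbouring miR-212-3p and miR-132-3p, both induced by CREB signalling, rose, the first from a mean of 7.44 to 9.34 and the second by 1.73. A brake on NF-kB signalling, miR-146b-5p, rose by 1.70. Among the miRNAs that fell were miR-1298-5p, from 11.73 ± 0.28 (SD, n = 3) to 9.94 ± 0.23 (SD, n = 4), and miR-448-3p, with a log2 difference of -1.65. Both are encoded in the introns of Htr2c, a serotonin receptor gene.

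In all, 134 miRNAs rose and 84 fell in WT lungs (limma), 70 and 24 of them by at least 2-fold. The other risers with the smallest p included miR-184-3p (1.99), miR-298-5p (2.08), miR-335-3p (1.19) and miR-301b-3p (1.65). The p53 target miR-34a-5p rose by 1.08. Other fallers were miR-328-3p (-0.68), miR-676-3p (-0.77) and miR-351-5p (-1.15, or -0.71 with quantile normalization). For every riser and faller given so far, all 4 bleomycin libraries lay beyond all 3 PBS libraries. Of the miRNAs named in advance, miR-155-5p, which drives inflammatory responses of leukocytes, rose by 1.06 (adjusted p = 0.000444). The red cell miRNA miR-451a fell, with a difference of -2.03 (adjusted p = 0.00408). Differences of 0.25 for miR-223-3p, -0.07 for miR-29b-3p, -0.13 for miR-126a-3p and 0.09 for let-7d-5p did not pass.

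Calls of 2 miRNAs named in advance lay near the threshold and changed with 1 library left out. The miR-146a-5p fall of -0.51 (adjusted p = 0.0311) was lost without WT bleomycin replicate 2 (-0.45, adjusted p = 0.0859) or 4 (-0.48, 0.0731), or WT PBS replicate 1 (-0.45, 0.116) or 2 (-0.38, 0.158), and with quantile normalization (-0.32, adjusted p = 0.168). That of miR-200c-3p, -0.38 (adjusted p = 0.046), was lost without WT bleomycin replicate 1 (-0.34, adjusted p = 0.0923), 2 (-0.35, 0.101) or 4 (-0.39, 0.0724), or WT PBS replicate 1 (-0.39, 0.094), 2 (-0.34, 0.14) or 3 (-0.40, 0.0571). With equal library medians the WT calls split into 110 up and 121 down, and with quantile normalization into 114 and 108. The median tested miRNA moved by 0.12 log2 in WT and 0.13 in R213G between the deposited scaling and equal medians. In the authors' deposited table, 11 miRNAs (9 up, 2 down) had a q-value under 0.05 in this comparison by the parametric test and 0 by the rank test, which gave 74 at an unadjusted p under 0.05. With 3 against 4 libraries the smallest p of the rank test was 0.0319. Such a q-value was hardly within its reach, so its 0 says little.

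**Figure D2:**
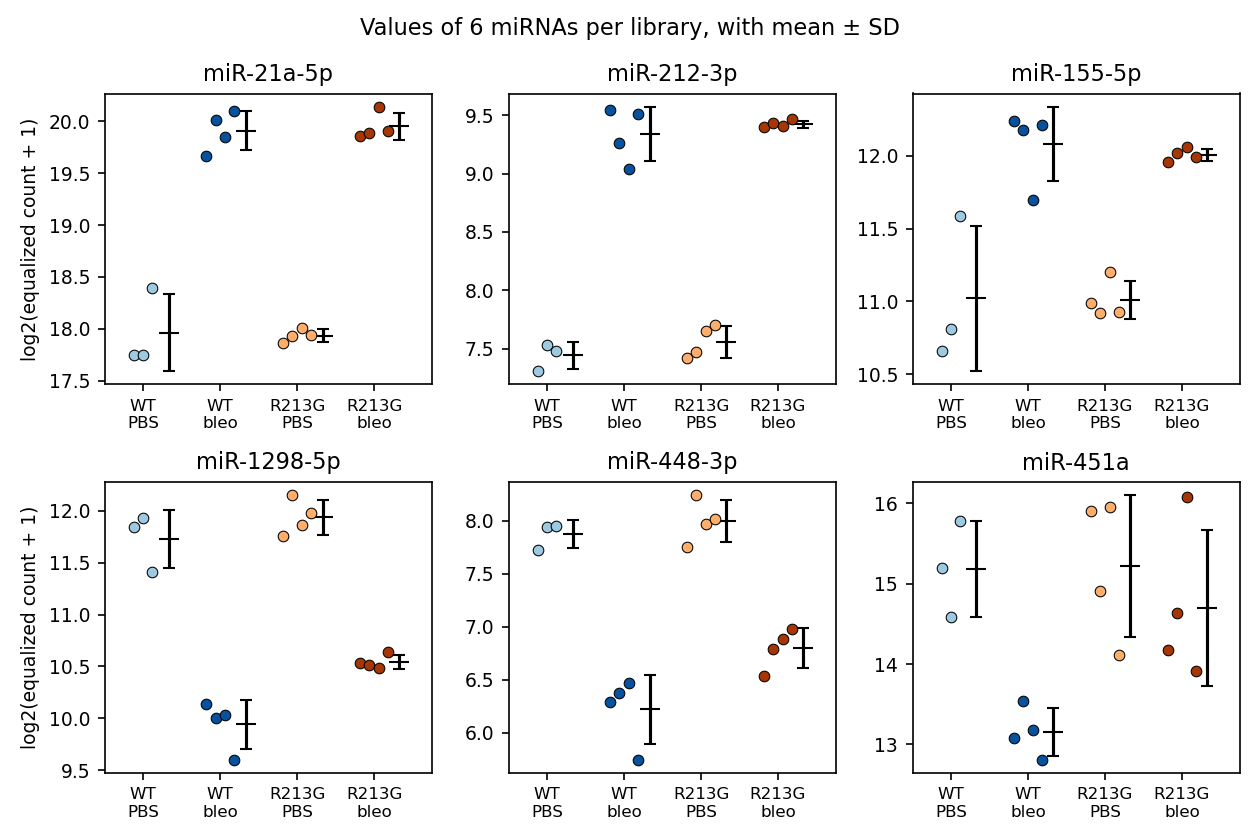
Values per library of 6 miRNAs, as log2 of 1 plus the equalized count, by group, each point 1 library and the bar the mean ± SD. After bleomycin miR-21a-5p, miR-212-3p and miR-155-5p are higher and miR-1298-5p and miR-448-3p lower in both genotypes, and miR-451a is lower in WT.

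The same comparison in R213G mice asks which miRNAs differ after bleomycin when EC-SOD carries the variant. Again miR-21a-5p rose, from 17.93 ± 0.06 (SD, n = 4) to 19.95 ± 0.13 (SD, n = 4), a log2 difference of 2.02 ± 0.13 (SE, adjusted p = 2.22e-08). The lipopolysaccharide-induced macrophage miRNA miR-147-3p rose by 3.69 ± 0.40 (SE, adjusted p = 4.14e-06). In WT it was higher too, at 9.95 to 10.37 after bleomycin against 6.28 to 8.84 after PBS, a log2 difference of 3.09. As in WT, miR-212-3p (1.86), miR-132-3p (1.60) and miR-146b-5p (1.84) were among the risers, and miR-1298-5p (-1.40) and miR-448-3p (-1.20) among the fallers.

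In R213G lungs 182 miRNAs rose and 162 fell (limma), 74 and 33 of them by at least 2-fold. Further risers were miR-335-3p (1.30), miR-184-3p (2.16), miR-298-5p (1.94) and miR-34a-5p (1.30), and further fallers were miR-26a-5p (-0.84, or -0.46 with quantile normalization), miR-31-5p (-0.82), miR-151-3p (-0.65, or -0.39) and miR-351-5p (-1.27). Every one of these had all 4 bleomycin libraries beyond all 4 PBS libraries. Of those named in advance, miR-155-5p rose by 1.00 (adjusted p = 0.000281) and miR-146a-5p fell, at -0.73 (adjusted p = 0.00136). The endothelial miR-126a-3p fell, at -0.41 (adjusted p = 0.0188), a call lost without R213G bleomycin replicate 4 (-0.28, adjusted p = 0.073) or with quantile normalization (-0.09, adjusted p = 0.506). The differences of -0.52 for miR-451a, -0.29 for miR-200c-3p, -0.18 for miR-223-3p, 0.24 for miR-29b-3p and 0.13 for let-7d-5p did not pass. Without R213G bleomycin replicate 3, at 16.08 for miR-451a against 13.91 to 14.63 in the other 3, miR-451a (-0.98, adjusted p = 0.0479) and miR-200c-3p (-0.42, adjusted p = 0.00582) passed, as did miR-200c-3p with a term for tag order (adjusted p = 0.0474). With equal library medians the calls split into 148 up and 199 down. The authors' deposited table had 160 miRNAs (98 up, 62 down) at a q-value under 0.05 by the parametric test and 0 by the rank test, which gave 373 at an unadjusted p under 0.05. With 4 against 4 libraries the smallest p of the rank test was 0.0211, so here too its 0 says little.

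Most called members of the inflammation-linked lists rose. Of 12 tested NF-kB-linked miRNAs, 7 rose, 1 fell and 4 did not pass in WT, and 8 rose, 1 fell and 3 did not pass in R213G, with the same numbers up and down adjusted over the list alone. Their median log2 difference was 1.28 in WT (camera, adjusted p = 0.000194, and with an estimated correlation adjusted p = 0.051) and 1.30 in R213G (0.000162, with an estimated correlation adjusted p = 0.0606). The member that fell, miR-146a-5p, is a feedback inhibitor of NF-kB signalling. Among 6 myeloid and pan-leukocyte miRNAs, 4 rose and 2 did not pass in WT, with miR-223-5p at 1.05, miR-511-3p at 1.25 and miR-142a-3p at 1.20. In R213G 3 rose and 3 did not pass, with miR-511-3p, encoded in a macrophage mannose receptor gene, at 1.74. The myeloid list passed in WT (adjusted p = 0.00311, with an estimated correlation adjusted p = 0.199) and not in R213G (adjusted p = 0.0577, or 0.0446 without R213G bleomycin replicate 1 and 0.0153 without the filter, and by fry 0.000649), and 4 and 3 rose adjusted over the list alone.

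Lymphocyte miRNAs were mixed. In WT 1 of 6 rose, 1 fell and 4 did not pass, and in R213G 1 rose, 4 fell and 1 did not pass (over the list alone 1 and 1, and 1 and 4). In R213G miR-150-5p, a miRNA of mature lymphocytes, fell, at -0.69 (with quantile normalization -0.39, adjusted p = 0.0702), and miR-181a-5p, at -0.74. With that normalization 2 fell in R213G. By camera the list passed in neither (adjusted p = 0.753 and 0.148), and by fry in R213G alone (0.924 and 0.0197). Its WT median of 0.06 became -0.06 with equal library medians.

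Called members of the fibrosis-linked lists went mostly in the direction of the list, and others did not pass. Of 14 pro-fibrotic miRNAs, 9 rose, 1 fell and 4 did not pass in WT (9 up and 2 down adjusted over the list alone), and 10 rose, 2 fell and 2 did not pass in R213G (10 and 2). With equal library medians 6 rose and 2 fell in WT, and 7 rose and 2 fell in R213G. Quantile normalization gave 8 and 0 in WT and 10 and 1 in R213G. Beside miR-21a, miR-214-3p rose by 0.71 and 0.86 and miR-409-3p by 0.91 and 0.86. The list passed in WT (adjusted p = 0.00311, with an estimated correlation adjusted p = 0.226) and in R213G (0.00126, with an estimated correlation adjusted p = 0.218). Of 15 anti-fibrotic miRNAs, 0 rose, 6 fell and 9 did not pass in WT (0 up and 7 down adjusted over the list alone), and 0 rose, 9 fell and 6 did not pass in R213G (1 up and 10 down). Among them miR-26a-5p fell, at -0.58 in WT (-0.25 with quantile normalization, adjusted p = 0.00453), and miR-27a-3p, at -0.49 in R213G, or -0.13 with quantile normalization (adjusted p = 0.286), which left 6 members down and 2 up there. The anti-fibrotic list passed in both (adjusted p = 0.000221 and 0.00359, with an estimated correlation adjusted p = 0.199 and 0.409). It shares miR-486a-5p and miR-486b-5p, near-identical copies whose reads are uncertain, with the erythroid list, and miR-133a-3p with the striated muscle list. Both of those lists had negative medians too, though not all of their members passed.

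Most erythroid miRNAs, a list meant for blood left in the lung, fell after bleomycin, but 5 of the 9 stand in other lists too. In each genotype 6 fell and 3 did not pass (6 also adjusted over the list alone), with medians of -2.03 in WT and -1.25 in R213G (adjusted p = 0.000221 and 0.0103, with an estimated correlation adjusted p = 0.286 and 0.489). In WT miR-144-5p fell, at -1.98, and miR-486a-3p, at -2.20. In each genotype the fallers included both strands of the near-identical copies miR-486a and miR-486b, so they are not separate results. The neighbouring miR-144 and miR-451a genes were grouped after the data were seen. Of their 3 tested members, 2 fell in WT and 1 in R213G (fry over 30 clusters, adjusted p = 0.0137 and 0.331). Striated and cardiac muscle miRNAs had medians of -0.93 and -0.94. In WT 2 of 7 fell and 5 did not pass, in R213G 4 fell and 3 did not pass, with 2 and 4 over the list alone. The muscle list passed in WT (adjusted p = 0.0119, with an estimated correlation adjusted p = 0.339), but not without WT PBS replicate 3 (0.116), and in R213G (0.0285, with an estimated correlation adjusted p = 0.489), but not without R213G bleomycin replicate 2 (0.0514). Its member miR-133a-3p fell in WT, at -1.52, or -0.79 without WT PBS replicate 3, and in R213G, at -2.18.

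The lists of structural cells differed. Of 8 smooth muscle and mesenchymal miRNAs, 6 fell and 2 did not pass in WT (8 down over the list alone), and 7 fell and 1 did not pass in R213G (7 over the list alone), with miR-100-5p at -0.47 and -0.50 and miR-125b-5p at -0.45 and -0.41. The list passed in both (adjusted p = 0.000221 and 0.00359, with an estimated correlation adjusted p = 0.0663 and 0.218). Of 13 epithelial miRNAs, 5 fell and 8 did not pass in WT (5 over the list alone), and 9 fell and 4 did not pass in R213G (10 over the list alone). There miR-205-5p, of basal epithelium, fell, at -1.91 in R213G and at -1.28 in WT, where its call was lost without WT PBS replicate 3 (-0.75, adjusted p = 0.0841). In R213G miR-429-3p fell, at -0.49, or -0.23 with quantile normalization (adjusted p = 0.0876). That normalization left 5 epithelial miRNAs down and 1 up in R213G, with medians of -0.11 in WT and -0.24 in R213G in place of -0.29 and -0.35. It left 4 and 5 smooth muscle miRNAs down. The epithelial list passed in both (adjusted p = 0.00311 and 0.00359, with an estimated correlation adjusted p = 0.316 and 0.425). Ciliated cell miRNAs went both ways. In WT 2 of 7 rose, 1 fell and 4 did not pass (3 and 1 over the list alone), in R213G 3 rose, 1 fell and 3 did not pass (3 and 1), and the list did not pass (adjusted p = 0.607 and 0.338). Its WT median of 0.08 became -0.04 with equal library medians. The ciliated cell miRNA miR-449c-5p rose by 1.82 and 1.95. Endothelial miRNAs did not pass in WT, all 4 of them, and 2 fell and 2 did not pass in R213G, with 0 and 2 down over the list alone (list adjusted p = 0.753 and 0.559), and the WT median of 0.11 became -0.01 with equal library medians.

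Most called members of both clustered lists rose, while many did not pass. Of 64 tested Dlk1-Dio3 miRNAs, an imprinted cluster active in the fetus and in mesenchymal cells, 21 rose, 1 fell and 42 did not pass in WT (21 and 1 adjusted over the list alone), and 32 rose, 1 fell and 31 did not pass in R213G (33 and 1). Examples are miR-380-3p (1.73) and miR-411-3p (0.88) in WT and miR-494-3p (1.17) and miR-134-5p (1.23) in R213G. The medians were 0.43 and 0.69 (adjusted p = 0.000221 and 3.4e-05, with an estimated correlation adjusted p = 0.448 and 0.489). Of 39 Sfmbt2 intronic miRNAs, near-identical copies whose individual values are uncertain, 8 rose and 31 did not pass in WT (8 over the list alone, 2 with quantile normalization), and 10 rose, 1 fell and 28 did not pass in R213G (8 and 0). That list passed in WT (adjusted p = 0.00577, with an estimated correlation adjusted p = 0.354) and not in R213G (adjusted p = 0.0779), where it passed without R213G bleomycin replicate 1 (0.0446) or R213G PBS replicate 1 (0.0339), and by fry (0.0197).

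By camera the growth and stress lists mostly did not pass. Fry, which asks another question, passed proliferation in WT (adjusted p = 0.0121), hypoxia and redox (0.0167 in WT and 0.0415 in R213G), miR-30 (0.0272 and 0.0415) and other organs in R213G (0.0124). The counts up and down in each were the same adjusted over the list alone, except that 4 miR-30 members fell in R213G. Of 17 proliferation-linked miRNAs, 6 rose and 11 did not pass in WT, and 7 rose, 2 fell and 8 did not pass in R213G (adjusted p = 0.0865 and 0.338), with 4 up and 1 down in WT and 5 up and 4 down in R213G at equal library medians, where the R213G median of 0.18 became 0.04. Examples are miR-20b-5p at 0.60 in WT (0.43 with quantile normalization, adjusted p = 0.0602) and miR-15b-5p at 0.52 in R213G. Of 10 p53 targets, 2 rose, 2 fell and 6 did not pass in WT, and 2 rose, 3 fell and 5 did not pass in R213G (adjusted p = 0.607 and 0.672). Their medians, -0.16 and -0.19, and means, 0.07 and 0.16, differed in sign. Both strands of miR-34a rose, miR-34a-3p by 1.19 and 2.10. Of 9 hypoxia and redox miRNAs, 1 rose, 2 fell and 6 did not pass in WT, and 1 rose, 3 fell and 5 did not pass in R213G (adjusted p = 0.109 and 0.338). The hypoxia-induced miR-210-3p did not pass (-0.19 and 0.07, adjusted p = 0.186 and 0.605), while the scarcer strand miR-210-5p fell in R213G, at -1.31. The list shares miR-144-3p and miR-144-5p with the erythroid list. Of 9 let-7 family members, 2 rose and 7 did not pass in WT, and 3 rose, 1 fell and 5 did not pass in R213G (adjusted p = 0.753 and 0.616). In the family let-7i-5p rose by 0.42 and 0.46, and the medians of 0.09 and 0.03 became -0.02 and -0.10 with equal library medians, with 1 up and 2 down in WT and 2 and 2 in R213G. Quantile normalization gave 3 and 1 in WT and 4 and 0 in R213G. Of 7 miR-30 family members, 2 fell and 5 did not pass in WT (adjusted p = 0.00577, with an estimated correlation adjusted p = 0.354), and 3 fell and 4 did not pass in R213G (adjusted p = 0.0533), with miR-30d-5p at -0.54 and -0.59 (the latter -0.33 with quantile normalization). In R213G that list passed without bleomycin replicate 1 (0.0392) or 3 (0.00952) or PBS replicate 2 (0.0457) or 4 (0.0322), with a term for tag order (0.0222) and without the filter (0.0125). Without the filter the proliferation (0.0337) and hypoxia and redox (0.0406) lists passed in WT. Of 8 miRNAs of other organs, 1 rose and 7 did not pass in WT, and 1 rose, 1 fell and 6 did not pass in R213G (adjusted p = 0.753 and 0.703). The riser was miR-217-5p, a pancreatic miRNA, at 1.54 and 2.92, from PBS values near the floor (0.70 to 2.91).

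Set side by side, the responses of the genotypes were alike in direction. Of the risers 104 were shared, with 29.8 expected from the numbers called, and of the fallers 73, with 16.6 expected. Across the 818 miRNAs, which are not independent replicates, the log2 differences correlated with a Pearson r of 0.780 and a Spearman rho of 0.729. Of 384 miRNAs called in either genotype, 361 had the same sign in both. Called in both with opposite sign was 1, miR-466b-3p, chosen after its values were seen, with 0.97 in WT and -0.81 in R213G. It has near-identical copies, so its reads are uncertain.

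The interaction contrast asks whether the variant altered the response, and 0 miRNAs passed (limma, smallest adjusted p = 0.399). At an unadjusted p under 0.05 there were 65, with 40.9 expected by chance. The smallest p belonged to miR-96-3p, with a difference of responses of -2.72 ± 0.64 (SE, adjusted p = 0.399), and miR-466b-3p, at -1.78 ± 0.44 (SE, adjusted p = 0.399). Of these, miR-96-3p lay near the floor, at 0.058, 0.059 and 1.435 in WT PBS and at most 3.402 in any library. Then came miR-150-5p (-0.76), miR-345-5p (0.88) and miR-5100 (-0.84), each with an adjusted p of 0.523. For miR-451a the responses differed by 1.51 ± 0.65 (SE, adjusted p = 0.601), and by 1.05 (adjusted p = 0.793) without R213G bleomycin replicate 3. The other miRNAs named in advance differed by -0.43 to 0.31. Called in 1 genotype alone were 206 miRNAs, 166 in R213G and 40 in WT, and 46 of them had an unadjusted interaction p under 0.05. The 95% interval of a difference between the responses, not adjusted over miRNAs, had a median half-width of 0.70 log2, and of 0.40 over the 287 miRNAs above log2 8. In the simulated data, with 200 changed miRNAs, 55.4% of interaction changes of log2 1 were recovered. If few miRNAs differ, the adjusted threshold is stricter, so that share can overstate the power of this contrast. No list passed (camera, smallest adjusted p = 0.245, and 0 with fry), with 1 lymphocyte and 1 Sfmbt2 miRNA lower over the list alone. Leaving out 1 library gave 1 list in place of 0, the Dlk1-Dio3 list without WT PBS replicate 2 (adjusted p = 0.00084), or the erythroid list without R213G bleomycin replicate 4 (0.0463) or R213G PBS replicate 1 (0.0384).

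**Figure D3:**
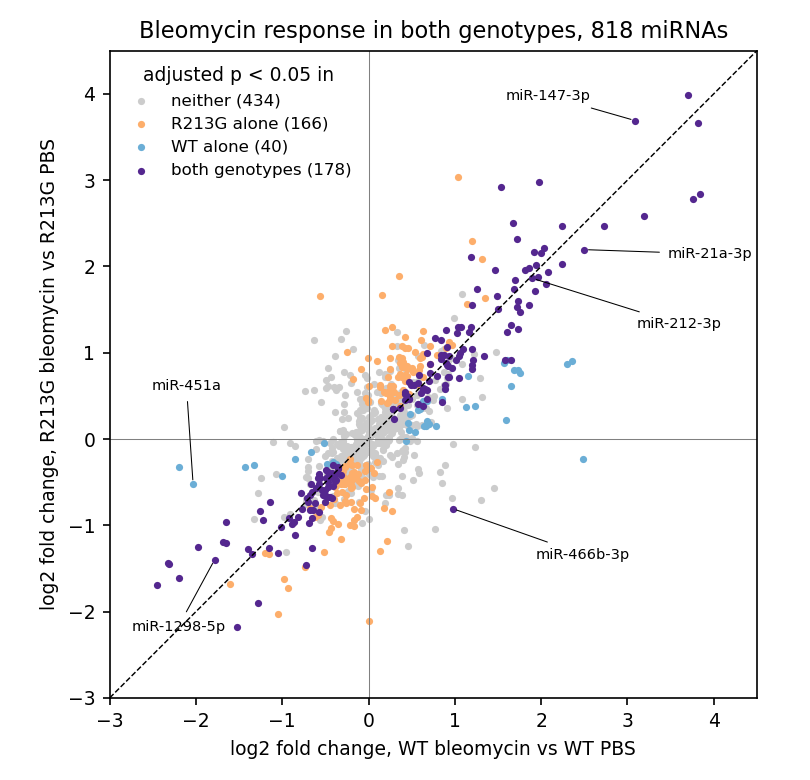
Log2 fold change after bleomycin in WT (horizontal) and in R213G (vertical) for 818 miRNAs, coloured by the genotype in which each was called. The dashed line marks equal change, 178 miRNAs were called in both genotypes, and miR-466b-3p is the 1 of them with opposite signs.

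R213G against WT after PBS asks whether the variant alone alters lung miRNAs. No miRNA passed, and levels of miR-21a-5p were 17.96 ± 0.37 (SD, n = 3) in WT and 17.93 ± 0.06 (SD, n = 4) in R213G. The pancreatic miR-217-5p had the smallest p, with a log2 difference of -1.41 ± 0.35 (SE, adjusted p = 0.622). Next were miR-301b-3p (0.63), miR-96-3p (1.68), miR-466g (0.67) and miR-142a-5p (0.38), all with an adjusted p of 0.622. In the PBS libraries miR-217-5p (0.70 to 2.91) and miR-96-3p (0.058 to 3.046) lay near the floor. The miRNAs named in advance differed by -0.10 to 0.27. By limma 0 were called, with 44 at an unadjusted p under 0.05 and 40.9 expected by chance. The authors' deposited table had 0 at a q-value under 0.05 by either test, with 60 and 47 at an unadjusted p under 0.05. The rank test could hardly reach such a q-value, since its smallest p was 0.0319.

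Although no member of any list passed over all tested miRNAs, 4 lists did by camera. Smooth muscle miRNAs were lower in R213G, with a median of -0.15 (adjusted p = 0.00351, with an estimated correlation adjusted p = 0.294), and Sfmbt2 miRNAs higher, with 0.37 (2.17e-06, with an estimated correlation adjusted p = 0.294). Proliferation miRNAs had a median of 0.12 (adjusted p = 0.0205, with an estimated correlation adjusted p = 0.534), and the call ended without WT PBS replicate 1 (0.0622), 2 (0.0863) or 3 (0.0526) or R213G PBS replicate 1 (0.0903) or 3 (0.208). Dlk1-Dio3 miRNAs had a median of -0.07 (adjusted p = 0.0205, with an estimated correlation adjusted p = 0.842). That call ended without R213G PBS replicate 2 (0.423) or without the filter (0.129), and without WT PBS replicate 3 the direction turned (0.0516). Other lists passed in altered fits, erythroid without R213G PBS replicate 4 (0.0101) and with the replicate block (0.0128), let-7 and myeloid without R213G PBS replicate 2 (0.0264 each) and miR-30 without WT PBS replicate 3 (0.0249). By fry 0 lists passed. Adjusted over the list alone, 1 myeloid and 2 lymphocyte miRNAs were higher and 1 miRNA of other organs lower.

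R213G against WT after bleomycin asks whether injured lungs differ by genotype. No miRNA passed, and miR-21a-5p (0.05) and miR-155-5p (-0.08) differed little. The smallest p belonged to miRNAs of the Htr2c introns, higher in R213G, namely miR-1298-5p, at 9.94 ± 0.23 (SD, n = 4) in WT and 10.54 ± 0.07 (SD, n = 4) in R213G, a difference of 0.59 ± 0.14 (SE, adjusted p = 0.219). Of the same introns were miR-1298-3p (0.70, adjusted p = 0.219), miR-1912-5p (1.42, adjusted p = 0.221) and miR-1912-3p (0.80, adjusted p = 0.232), while miR-6956-3p was lower (-0.94, adjusted p = 0.221). The red cell miR-451a differed by 1.55 ± 0.44 (SE, adjusted p = 0.232). The other miRNAs named in advance differed by -0.22 to 0.27.

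By limma 0 were called between the injured groups, with 97 at an unadjusted p under 0.05 and 40.9 expected by chance, and 1 was called, miR-1298-3p, without WT bleomycin replicate 1 (0.85, adjusted p = 0.0217). The authors' deposited table had 0 at a q-value under 0.05 by either test, with 80 and 79 at an unadjusted p under 0.05. The rank test could hardly reach such a q-value, since its smallest p was 0.0211. By camera 2 lists passed. Erythroid miRNAs were higher in R213G, with a median of 0.87 (adjusted p = 0.00192, with an estimated correlation adjusted p = 0.795), a call that ended without R213G bleomycin replicate 2 (0.0566), and 2 of them were higher adjusted over the list alone. Sfmbt2 miRNAs had a median of 0.23 (adjusted p = 0.0136, with an estimated correlation adjusted p = 0.795), which ended without R213G bleomycin replicate 2 (0.165) or 4 (0.0554). By fry 0 lists passed, and 1 striated muscle miRNA was higher over the list alone. Without WT bleomycin replicate 3, 4 lists passed by camera, with let-7 and lymphocyte miRNAs (0.0318 each) added, and let-7 miRNAs also passed without WT bleomycin replicate 4 (0.0176) or R213G bleomycin replicate 4 (0.0353).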

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

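The tests of a wrong label, of mixed RNA, of tag order, of WT PBS replicate 3 together with the number of PBS libraries, of RNA from other organs and of a milder injury were chosen only after the result was seen.

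Other splits of the same libraries were counted for each comparison. For the WT response, 1 of 35 splits, the real one, gave at least 218 calls, and the highest other gave 105. In that other split WT bleomycin replicate 1 stood with the 3 WT PBS libraries. For the R213G response 1 of 35 gave at least 344, the highest other 4. Both counts argue against chance but cannot exclude it, because 1 of 35 is the smallest share these splits can give. Splits decide nothing for the comparisons with 0 calls, because every split gives at least 0. These were R213G against WT after PBS (35 of 35, highest other 10) and after bleomycin (35 of 35, highest other 0) and the interaction (100 of 100 drawn, highest other 79). The split with 79 set 6 bleomycin libraries and 1 PBS library on the same side, so it can carry the bleomycin response. The PBS split with 10 calls set WT PBS replicate 3 with R213G PBS replicates 1 and 3. These had the highest red cell miR-451a of the PBS libraries (15.78, 15.91 and 15.95, others 14.11 to 15.20). They also scored lowest of the PBS libraries on the second principal component (-7.33, -6.00 and -5.76). That split was picked as the highest, and whether its calls go beyond chance was not tested.

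WT PBS replicate 3 lay toward the bleomycin libraries on the first principal component. Its place between the other WT PBS libraries (0) and WT bleomycin (1) was taken over 27 of the 182 miRNAs that rose in R213G. These 27 were also chosen for their level in the other WT PBS libraries and for a rise from there to WT bleomycin. The other WT PBS libraries thus set both the choice and the 0 of this scale, which can push replicate 3 above 0. The place of replicate 3 had a median of 0.161 and an upper quartile of 0.336, which argues against a bleomycin lung under the wrong label. Mixed RNA of a lung like the WT bleomycin mean would place every riser alike. The interquartile range was 0.236, against 0.0764 and 0.0711 for the other WT PBS libraries, with miR-212-5p at 0.000535 and miR-155-5p at 0.511. The choice of miRNAs used the other WT PBS libraries, so their narrower ranges may understate the spread. This comparison therefore does not decide on mixed RNA. Single lungs can also differ from the WT bleomycin mean (miR-18a-5p 9.14 to 11.28 in WT bleomycin), and mixing with 1 such lung was not tested. Depth cannot be told apart, because the deepest minus the shallowest library gave -0.298, 0.443 and -0.0591 in the other groups (median -0.0591), around a shift of 0.345. Tag order, which runs together with depth in every group, cannot be told apart either. That library has the last tag number of its group, and later minus first tags gave -0.179, 0.325 and -0.0354 in the other groups (median -0.0354). A mild lung response of that mouse, or its sex, stays open and was not tested. In several striated muscle miRNAs WT PBS replicate 3 lay away from the bleomycin libraries, above every other library. Its miR-133a-3p was 16.24, against 13.88 to 14.81 in the other PBS and 11.72 to 13.72 in the bleomycin libraries. Its miR-133b-3p was 10.17, against 7.14 to 7.85 and 6.28 to 7.86. Its miR-1a-3p was 11.57, against 9.19 to 10.68 and 7.73 to 9.72. Its miR-1b-5p was 8.16, against 5.65 to 7.09 and 4.31 to 6.32. Its miR-208b-3p was not raised (9.31, other PBS libraries 9.76 to 10.16). What lay behind these values was not tested.

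More miRNAs were called in R213G (344) than in WT (218). With 3 of the 4 R213G PBS libraries the calls were 289 to 324 (median 299.5), so the number of PBS libraries alone does not account for the gap. Without WT PBS replicate 3 there were 251 WT calls, so that library alone does not either. With 2 PBS libraries on each side, R213G had 197 to 271 calls (median 235) and WT 251, so both together may account for it. A stronger response in R213G stays open, and the interaction itself called 0 (65 at an unadjusted p under 0.05 by limma).

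The 9 tested Htr2c intronic miRNAs, on chromosome X, were higher in R213G than in WT after bleomycin, with a median difference of 0.70 (0.44 to 1.42) and 6 of 9 without overlap of the libraries, against 3.06% of all tested and 1.43% by chance. After PBS their median difference was 0.20 in the same direction, and the median of their interaction was 0.45. All 9 share 1 host gene, so they are not independent, and miR-448-5p lay near the floor (0 to 2.91). The group was chosen after the data were seen, the exact permutation p of its median was 0.0286, two-sided over 35 splits and the smallest they can give, and the tests over 30 clusters disagree. After bleomycin the genotypes differed by fry (adjusted p = 0.00336) and camera (3.89e-11) and not with an estimated correlation (0.0577). The interaction passed by camera (0.000151), and not by fry (0.202) or with an estimated correlation (0.767). Against a smaller fall of all lowered miRNAs, 66 others had a median of -0.11 (upper quartile 0.02). With the depth covariate the median was 0.755, which cannot decide on depth. If counts were equalized within each group, as inferred here, the value of a single read follows depth only within a group. Against a milder injury in R213G as the whole cause, the R213G response over the WT response had a median of 0.943 (lower quartile 0.711) over 209 other miRNAs called in WT, and 0.662 over the Htr2c miRNAs. RNA of other organs cannot be told apart, because the 8 members of that list went both ways (median 0.016, quartiles -0.718 and 0.257). The order of the tag numbers cannot be told apart from genotype, because all R213G libraries come before all WT libraries in it. Sex, which is not known per mouse, stays open and untested.

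Single libraries that stood far from the other 3 of their group came to 32 of 528 groups tested, or 6.06%, where chance alone gives 26.4. Each ratio below is the library's gap to its nearest neighbour over the range of the group, above Dixon's critical value at the 95% level.

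WT bleomycin replicate 1 had 9 of them. It was highest for miR-328-3p (0.83), miR-205-5p (0.833), miR-150-5p (0.892) and miR-467d-5p (0.854). It was lowest for let-7c-5p (0.87), miR-411-3p (0.836), miR-326-3p (0.855), miR-187-3p (0.925) and miR-297a-3p (0.849). WT bleomycin replicate 2 was highest for miR-382-5p (0.95). WT bleomycin replicate 3 was lowest for miR-155-5p (0.891) and highest for miR-30b-5p (0.881). WT bleomycin replicate 4 was lowest for miR-431-3p (0.902).

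R213G PBS replicate 1 was lowest for miR-21a-3p (0.84) and miR-511-5p (0.846) and highest for let-7i-5p (0.862). R213G PBS replicate 2 was highest for miR-335-3p (0.94), miR-1264-3p (0.847), miR-100-5p (0.925) and miR-382-3p (0.852). R213G PBS replicate 3 was lowest for miR-328-3p (0.977), miR-200b-3p (0.9) and miR-92a-3p (0.876) and highest for miR-142a-3p (0.909) and miR-96-3p (0.938).

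R213G bleomycin replicate 1 was highest for the liver miRNA miR-122-5p (0.836), at 8.96 against 4.24 to 5.01. That miRNA ranged from 3.69 to 8.97 over the 15 libraries. R213G bleomycin replicate 2 was lowest for miR-335-3p (0.864) and miR-667-3p (0.849). R213G bleomycin replicate 3 was highest for miR-342-3p (0.913) and miR-1b-5p (0.837). R213G bleomycin replicate 4 was highest for miR-217-5p (0.846) and miR-466g (0.897).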

How the results depend on the processing

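The depth covariate and the tag order term were chosen after the data were seen. Of 158 called values of named miRNAs, 123 stayed on the same side of the threshold under every alternative run. Over 3244 alternatives, 3122 did, 122 lost the call and 0 reversed. WT calls ranged from 167 without WT PBS replicate 2 to 251 without WT PBS replicate 3, R213G calls from 289 without R213G PBS replicate 4 to 342 without R213G bleomycin replicate 2. Other settings gave 177 to 281 and 307 to 408, the highest at an adjusted p under 0.1. R213G against WT after PBS and the interaction gave 0 calls under all settings. The correlation of the responses was 0.633 without the filter, which adds low miRNAs (1416 tested). After bleomycin, R213G against WT gave 2 calls with array weights, miR-1298-3p (0.81) and miR-1298-5p (0.68), each at an adjusted p of 0.0167, and 0 to 1 with 1 library left out; the cause was not tested. With an estimated correlation, 0 lists passed in the WT response, the R213G response, R213G against WT after PBS and after bleomycin. The estimates ran from -0.058 (other organs) to 0.7 (miR-30), most of them above the preset 0.01. Those camera runs differ in nothing else, so the passes rest on the preset. Fry passed 14 in the R213G response and 0 in both genotype comparisons, and the cause of that was not tested. Leaving out 1 library gave 0 to 4 lists for R213G against WT after bleomycin and 0 to 1 for the interaction. The Dlk1-Dio3 list of R213G against WT after PBS reversed without WT PBS replicate 3 (adjusted p = 0.0516), within 1.35e-07 to 0.423 over libraries left out; the cause was not tested. Pairing of same-numbered libraries was not clear. Of 21 such pairs 9 had a correlation over 0.1 (-0.145 to 0.262), with a median of 0.065, against -0.019 for other numbers. Of 15 libraries 6 matched their own number best, so a weak pairing cannot be excluded. The replicate block gave 215 and 348 calls in the bleomycin responses and 0 in the rest, and the tag order term 232 and 361, and 0 in the rest. Depth limits miRNAs near the floor, where a single read takes a value of 0.734 to 1.283. Alternatives on counts (edgeR RLE, DESeq2, recovered reads) were not run, since the table holds no counts.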

Other observations

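The groups of neighbouring miRNA genes in this part (30 clusters within 10 kb, by GENCODE M21 on GRCm38) and the tag order term were chosen only after the result was seen.

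A group of miRNAs on chromosome X known from the testis, the Mir743 to Mir465 cluster, rose in lungs after bleomycin. All 7 tested members rose in each genotype, with medians of 3.70 in WT (fry, adjusted p = 0.000149, camera with an estimated correlation adjusted p = 0.255) and 2.79 in R213G (0.000256, with an estimated correlation adjusted p = 0.378). In all 8 bleomycin libraries miR-470-5p stood at 4.63 to 5.64, and in the 7 PBS libraries at 0 to 3.50. The levels were low, miR-743b-3p and miR-881-3p were listed at 0 in all 3 WT PBS libraries, and miR-465b-5p and miR-465c-5p are near-identical copies, so their reads are uncertain.

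Of the other clusters, 4 are given here, picked for their differences. In the Mir450b to Mir322 cluster, which holds miR-503 and miR-351 and is linked to cell cycle arrest, 8 of 10 members fell in WT and 9 in R213G, with a median of -0.71 in each (fry, adjusted p = 0.000118 and 6.03e-05, camera with an estimated correlation adjusted p = 0.192 and 0.273). In the Mir449 cluster of ciliated cells, 3 of 5 rose in WT and 5 in R213G, with medians of 1.21 and 2.297 (0.00285 and 0.000227, with an estimated correlation adjusted p = 0.353 and 0.374). Its miR-449b (0.04 to 2.89) and miR-449c-3p (0 to 2.57) lay near the floor in R213G PBS, so the gap between these medians is uncertain. The abundant miR-449c-5p rose by similar amounts in both genotypes. All 4 members of the Mir212 to Mir132 cluster rose in each, with medians of 1.82 and 1.73 (4.97e-08 and 4.2e-08, with an estimated correlation adjusted p = 0.0784 and 0.273). The interaction was not past the threshold for any of these (fry, adjusted p = 0.871 for Mir743, 0.999 for Mir450b, 0.871 for Mir449 and 0.871 for Mir212). Of the Htr2c intronic miRNAs, 9 of 9 fell in WT and 7 of 9 in R213G, with medians of -1.65 and -0.96 (fry, adjusted p = 2.29e-06 and 5.47e-05, camera with an estimated correlation adjusted p = 0.0784 and 0.273).

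Libraries also differed along the order of the tag numbers in the column names. In R213G the first 4 tags are bleomycin and PBS replicates 1 and 3, and the next 4 are replicates 2 and 4. A term for the first 2 tags of each group against the rest called 13 miRNAs (limma, 110 at an unadjusted p under 0.05, 40.9 expected), 8 of them higher in the first tags. Of 100 choices of 2 libraries per group, 1, the real one, gave as many, the highest other gave 8, and without the WT PBS libraries 9 were called. The differences were 3.96 for miR-654-3p and 3.16 for miR-3966 (adjusted p = 5.13e-08 each) and -0.76 for miR-378a-3p (adjusted p = 0.0009), each without overlap in all 4 groups. The value of a single read, which follows depth, was higher in the first tags in every group (1.141 and 1.188 against 0.734 and 0.8051 in R213G bleomycin), so depth and tag order run together here. What the tags mark is not given in the sources used here. The term works within groups and left the genotype comparisons and the interaction at 0 calls. All R213G tags come before all WT tags, so any effect of the order between the genotypes cannot be told apart from genotype in any comparison of R213G with WT.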
